A study of Mus musculus with 2 samples.

How the data were processed

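The series holds ATAC-seq of sorted basal epidermal cells of the mouse in 2 libraries, 1 control and 1 ablation. Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2 2.3.4.2, Picard, MACS2 2.1.0.20151222 and HTSeq with build mm10; their roles and settings are not given in the sources used here. The authors deposited 1 table with a normalized signal per peak and library, with no gene column. Every value in each column was a whole multiple of 1 step, within 0.1 of a read (0.706 in control and 0.907 in ablation), so the deposited signal is reads per peak divided by 1 factor per library, and whole reads were recovered. The method behind the factors and the meaning of the selection of peaks are not stated.

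Columns were matched to samples by name. The control column carries the number 2, which its sample title does not, and the other column says Exp rather than Abl; it was taken as ablation since only 1 sample is not a control. The table had 116411 rows, of which exact repeats of a peak were merged, leaving 84594 peaks with a median length of 551 bp (124 to 8291). The 3 mitochondrial peaks were left out of all comparisons. Coordinates are as in the table; whether its starts count from 0 or 1 is not stated. Reads in all peaks were 18402788 in control and 18127119 in ablation, and a count of 0 (3 reads) allows up to 2.12 and 2.72 normalized reads.

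The log2 ratio of ablation to control was computed with a pseudocount of 1 on peaks whose mean signal reached the 10th percentile (13.96 normalized reads), leaving 76147. With 1 library per group the criterion was size, 2-fold, without a test. Intervals are exact Clopper-Pearson intervals of the recovered reads, for counting error only; PCR copies are not independent molecules.

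Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10. Since the deposited table lacked the gene annotation that the planned design relied on, each peak was assigned to every protein-coding gene it overlaps, or else to the nearest within 50 kb; 66485 tested peaks were assigned to 16276 genes. The gene table has no strand, so promoters were replaced by gene ends, within 1 kb of either end of a gene. A gene's value is the log2 ratio of its summed signal. For each of 27 lists (381 genes, all matched by symbol, 360 with a tested peak) the median was placed among 10000 random lists matched on deciles of summed signal. The planned motif comparison needs a genome sequence; none was used here, and it was not run.

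Named peaks are the 12 highest and 12 lowest log2 ratios, 1 per gene, among tested peaks of at least median signal, with predicted genes left out of the text. Named genes are the 2 highest and 2 lowest of each list; all AP-1, EGF receptor family and wound keratin members were eligible, and 1 gene that the rule names is not reported here. Lists, thresholds and this rule were fixed before the data were examined.

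The steps were tested on simulated reads for 84591 peaks with 200 changed by a known size, 50 per size. Of 2-fold gains 46% were recovered, as were 46% of 2-fold losses, 100% of 4-fold gains and 82% of 4-fold losses. The 4-fold losses that were missed (9 of 50) had been removed by the low-signal filter, since a loss in ablation lowers the mean of both libraries; 100% of the 41 kept were recovered. The first pass criterion asked for 85% of all 4-fold changes and was not met; it was then applied to peaks kept by the filter. The filter therefore favoured gains in the simulation, which changed ablation alone from a shared baseline. On the deposited values it treats both libraries alike. Higher peaks made up 67.3% of changed peaks without the filter and 70.4% with it, and counts without it are given among the alternatives. Of unchanged peaks 0.378% passed 2-fold, from counting error alone. The list step was checked apart, on independent normal values with a trend across the matched groups, not on reads, peaks or genes. There 4% of 200 null lists fell outside the central 95%. That check does not cover genes that share peaks or a spread that changes with signal.

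Alternatives covered the pseudocount, the filter, the scaling, the fold threshold, autosomes alone, the definition of a gene's value and the matching of random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Columns left unused numbered 0.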

Results

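Open chromatin was profiled by ATAC-seq in basal cells of mouse skin epidermis, sorted for high α6 integrin, absence of CD34 and Lrig1, and the fluorescent reporters of K14 lineage tracing. ATAC-seq marks accessible DNA by the insertions of a transposase. There was 1 library from control epidermis and 1 library from epidermis in which basal lineage cells had been ablated. The deposited table held 84594 distinct peaks, 84591 of them nuclear. Reads in nuclear peaks came to 17056996 in the control library and 12463908 in the ablation library, with medians of 76 and 62 reads per peak. The mitochondrial genome took a further 7.31% of the reads in peaks in control and 31.2% in ablation. With 1 library per group no spread between animals could be measured, so no difference was tested and no p-value is given for the conditions. Intervals are 95% intervals for counting error only.

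The comparison of ablation with control asks how chromatin accessibility of basal cells differs when the tissue expands clonally after cell loss. Regulators of epithelial-mesenchymal transition (EMT) had the highest median log2 ratio of ablation to control among the 27 gene lists. Their median log2 ratio was 0.59, with Hmga2, an architectural chromatin protein, at 2.22-fold (1.88 to 2.62) and Twist2, a transcription factor, at 2.68-fold (1.3 to 5.8). Inflammatory and NF-kB genes had a median of 0.14, led by the monocyte chemokine Ccl2 at 1.88-fold (1.68 to 2.11). Hair follicle stem cell genes had a median of 0.13, with the transcription factor Sox9 at 1.82-fold (1.62 to 2.05). With each library divided by its total over the table, the inflammatory and hair follicle medians were -0.20 and -0.21. Genes of spinous differentiation, the first suprabasal programme of keratinocytes, lay lowest, with a median of -0.24.

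Across the 76147 tested peaks, 3412 (4.48%) were at least 2-fold higher in ablation and 1432 (1.88%) at least 2-fold lower, while 79.5% lay within 1.5-fold. Drawing both libraries from 1 shared rate per peak gave on average 133 peaks higher and 149 lower from counting alone. The draw holds no other variation between libraries and no selection of peaks. It therefore does not measure how many peaks would differ between libraries of the same condition. The changed peaks were weak, with a median signal of 24.5 normalized reads for the higher and 24.3 for the lower peaks against 72.6 for the rest. The median log2 ratio declined with signal, from 0.20 in the lowest signal decile to -0.18 in the highest. Higher peaks made up 70.4% of changed peaks as deposited. After a loess correction, which by construction centres the ratio at every signal level and evens the split, the counts were 2366 higher and 2122 lower (52.7% higher). With each library divided by its total over the table, mitochondrial reads included, 1341 peaks were higher and 4232 lower (24.1% higher), a shift of -0.33 at the median that moves all peaks and genes nearly alike. Centring on strong gene-end peaks gave 5367 and 805 (87.0% higher), a shift of 0.18. How the deposited peaks were selected is not stated, and the counts describe that selection. Of the higher peaks 1790 sat in 1 block of the table in which 90.2% of peaks were higher in ablation, and the block with most peaks alone gave 1610 higher and 701 lower.

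**Figure D1:**
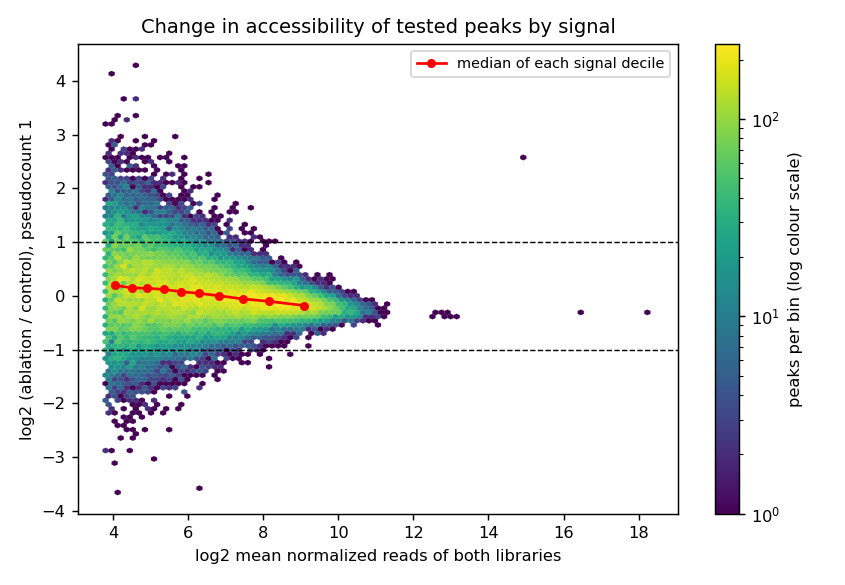
Each hexagon counts tested peaks by log2 mean normalized reads of both libraries (horizontal) and log2 ratio of ablation to control (vertical). Dashed lines mark 2-fold, and the red decile medians go from 0.20 at the lowest signal to -0.18 at the highest.

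Of the 27 gene lists, 7 lay at or above the 97.5th percentile of random lists matched on summed signal and 1 lay at or below the 2.5th. In 20 draws of both libraries from 1 shared rate per peak, counting alone gave on average 0.5 lists above and 0.55 below. At most 2 lists lay above and 2 below in a draw, so 1 list below is no more than counting alone can give. When the random lists were matched on mean signal per peak instead, 3 lists stayed above: EMT regulators, inflammatory genes and hair follicle stem cell genes. In the EMT list 10 of 11 genes had ratios above 1, some of them with counting intervals that include 1. Of its 35 peaks 7 (20%) were at least 2-fold higher against 1 lower. The share higher was 4.48% of all tested peaks and 14.2% in the lowest signal decile, a difference that was not tested. Hmga2 had 3 of 5 peaks at least 2-fold higher, the furthest on chromosome 10 at 120421988 to 120422565 in the gene body, with 36.7 normalized reads in control and 94.3 in ablation. The value of Twist2 rests on 1 peak with 12 and 25 reads. Zeb2, a repressor of E-cadherin, stood at a log2 ratio of -0.42 with an interval that includes no change, and Zeb1 at 0.00. With peaks outside gene ends alone, the EMT list lay at the 76.9th percentile.

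The inflammatory list had 11 of 18 genes above 0, and its median was -0.20 under division by the table total. That division shifts all genes nearly alike, so the place among random lists was nearly fixed (99.99th percentile). With gene-end peaks alone the list lay at the 86.4th percentile, and with the highest peak per gene at the 94.5th. Ccl2 had 4 of 7 peaks at least 2-fold higher, and Il19, a cytokine of the interleukin 10 family, reached 1.62-fold (1.39 to 1.88). Ccl20, which attracts Langerhans cell precursors, stood at -0.31 and the apoptosis inhibitor Birc3 at -0.27. In the hair follicle stem cell list 9 of 14 genes lay above 0, and 9 of its 130 peaks were at least 2-fold higher with 0 lower. Its median was -0.21 under division by the table total, at the 99.96th percentile, a place again nearly fixed by the shift of all genes. With gene-end peaks alone the list lay at the 93.0th. The absence of CD34 in the sort selects against bulge stem cells. Foxi3, a transcription factor of hair placodes, was at 1.94-fold (1.47 to 2.58) from 1 peak, and Sox9 had 2 of 6 peaks at least 2-fold higher. Postn and Fgf18 were lowest, at -0.17 and -0.10.

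**Figure D2:**
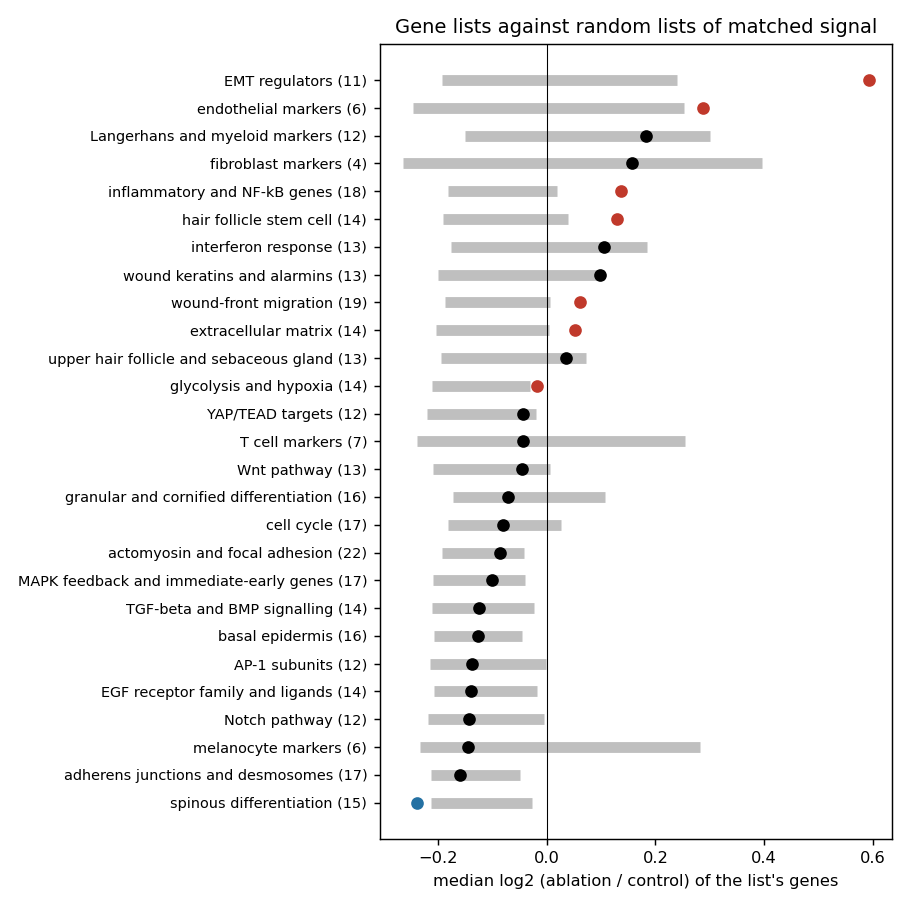
Points are median log2 ratios of ablation to control for each list, with the number of measured genes in brackets, and grey bars hold the central 95% of 10000 random lists matched on summed signal. Red points (7 lists) lie at or above the 97.5th percentile and the blue point (spinous differentiation) at or below the 2.5th; after division by the table total the EMT median, 0.25, is the 1 median above 0.

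Another 4 lists lay above the random lists matched on summed signal but not above those matched on mean signal per peak. Wound-front migration genes had a median of 0.06 (-0.28 with the table total), from Flrt2 at 0.77 and fibronectin (Fn1) at 0.61 to the protease Mmp10 at -0.46 and Flrt3 at -0.29. Fn1 and Flrt3 each rest on 1 peak. Extracellular matrix genes had a median of 0.05 (-0.29 with the table total), with the collagen crosslinker Loxl2 at 0.90 and nidogen (Nid1) at 0.86, and thrombospondin (Thbs1) at -0.48 and laminin Lamb1 at -0.17. Glycolysis and hypoxia genes had a median of -0.02, which was 0.16 with centring on strong gene-end peaks; Vegfa and Egln3 were at 0.30, and Hif1a and Pgk1 at -0.21 and -0.18. Endothelial markers had a median of 0.29 (-0.04 with the table total) over 6 genes.

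Among epidermal programmes, 2 of 15 spinous genes had log2 ratios above 0, where the median over all genes was -0.07. Of 17 adherens junction and desmosome genes, a list inside the random range, 1 lay above 0. The spinous median of -0.24 lay a little below the lower limit of the random lists, -0.21. Krt2, a suprabasal keratin, was at 0.757-fold (0.689 to 0.830) with 2 of 10 peaks at least 2-fold lower, and Sbsn at 0.762-fold (0.718 to 0.808). Ptgs1 was highest, at 0.18. The spinous list lay at the 0.46th percentile, at the 4.57th with gene-end peaks alone and at the 10.4th when peaks within 5 kb of a gene alone were used. Basal epidermis genes had a median of -0.13, inside the random lists except with gene-end peaks alone (99.1st percentile), with the hemidesmosome genes Col17a1 at -0.35 and Itga6 at -0.27 and with Krt5 at 0.21 and Igfbp2 at 0.17. Granular and cornified genes had a median of -0.07, with Lce3a at 0.95 and Rptn at 0.88 above and Sprr2a1 at -0.41 and Tgm1 at -0.39 below. Lce3a rests on 1 peak with 28 and 43 reads. Sprr2a1 rests on 1 peak with 38 and 22 reads, and its interval includes no change. Adherens junction and desmosome genes had a median of -0.16, with Perp at -0.30 and desmoplakin (Dsp) at -0.29, and actomyosin and focal adhesion genes -0.09, with Rhoc at 0.77 and Myh9 at -0.29; both lists lay inside the random range, though the actomyosin list lay at the 98.5th percentile after the loess correction and at the 98.6th with the highest peak per gene.

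**Figure D3:**
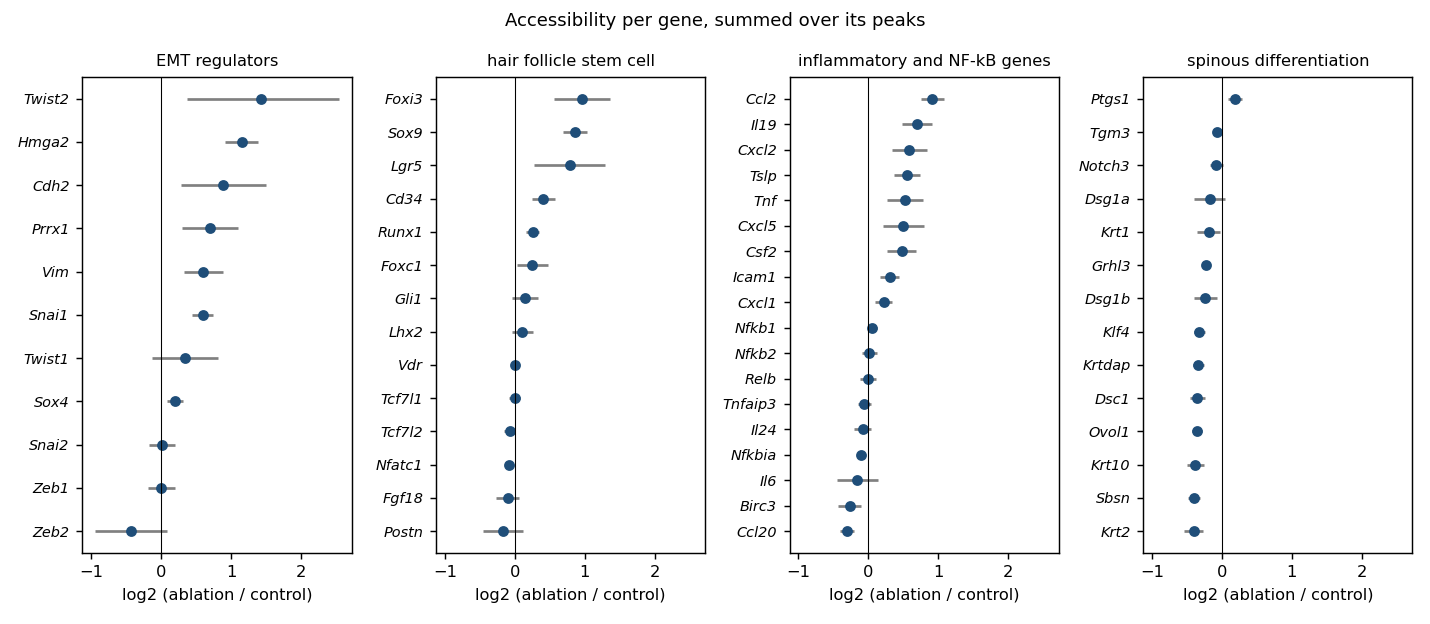
Points give the log2 ratio of ablation to control per gene, summed over its peaks without a pseudocount, and lines its 95% counting interval, for 4 lists. Of the EMT genes 10 of 11 lie above 0 in the deposited scaling, some with intervals that include 0, and 14 of the 15 spinous genes are drawn.

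AP-1 subunits, transcription factors induced by stress and growth signals, were not set apart, with a median of -0.14 at the 33.0th percentile. Within the list Atf3 was at -0.41, Fosb at -0.31, Fos at -0.28 and Fosl2 at -0.25, while Batf3 was at 0.41, Batf at 0.34 and Jdp2 at 0.28. EGF receptor family genes had the same median, -0.14, at the 32.5th percentile, and lay at the 1.46th with the highest peak per gene. Of their 140 peaks 9 (6.43%, against 4.48% of all tested peaks, a difference that was not tested) were at least 2-fold higher and 0 lower. The higher ones included 2 of 9 peaks of the ligand Ereg (1.54-fold, 1.39 to 1.71), 3 of 18 of Tgfa and 2 of 27 of Nrg1. Egfr itself was at 0.913-fold (0.875 to 0.952), a log2 ratio of -0.13, where the median over all genes was -0.07. Wound keratins and alarmins had a median of 0.10 at the 97.0th percentile. That place depended on the processing, from the 99.5th percentile with the filter at the 25th percentile to the 57.8th after the loess correction and the 15.1st with peaks outside gene ends alone. Lcn2, an iron-binding antimicrobial protein, was at 2.14-fold (1.3 to 3.6) from 1 peak, Krt6a at 1.21-fold (1.10 to 1.33), Krt17 at 1.12-fold (1.05 to 1.20) and Krt16 at 0.904-fold (0.830 to 0.984).

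The remaining signalling lists lay inside the random range matched on summed signal. Interferon response genes had a median of 0.11. After the loess correction with random lists matched on mean signal per peak, they lay at the 98.3rd percentile. Oas1a was at 1.34, from 1 peak with 23 and 47 reads, and Mx1 at 1.02, against Stat2 at -0.38, also from 1 peak. MAPK feedback genes had a median of -0.10, TGF-beta and BMP genes -0.12, Notch pathway genes -0.14, Wnt pathway genes -0.05, YAP/TEAD targets -0.04 and cell cycle genes -0.08. The YAP/TEAD list lay at the 98.3rd percentile when a gene took the median of its peaks. Single members of these lists stood apart from their medians in both directions. Above were the YAP/TEAD target Ccn2 at 0.85 and the Notch effector Heyl at 0.68, each from 1 peak, the activin gene Inhba at 0.63 and the Wnt antagonist Nkd1 at 0.50. Below were Id1 at -0.38, Hey1 at -0.31, Etv5 at -0.30, Fzd1 at -0.29 and Amotl2 at -0.26.

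Markers of other cell types differed in direction. The gate on the lineage reporters selects against cells outside the epithelium, and the absence of Lrig1 against the upper hair follicle. Endothelial markers ranged from Tie1 at 2.36-fold (1.89 to 2.95) and Flt1 at 1.47-fold (1.33 to 1.63) to Tek at 0.646-fold (0.569 to 0.733). Langerhans and myeloid markers had a median of 0.18, T cell markers -0.04, melanocyte markers -0.14, fibroblast markers 0.16 over 4 genes, and upper hair follicle and sebaceous gland markers 0.03, all inside the random range as reported. Langerhans and myeloid markers lay at the 99.1st percentile of random lists matched on the number of peaks, and melanocyte markers at the 1.42nd with gene-end peaks alone.

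Among peaks of at least median signal, a peak assigned to Tie1 on chromosome 4 at 118472442 to 118473070, in the gene body of this endothelial receptor, was 6.16-fold higher in ablation (3.94 to 10.0), from 24 to 115 reads. Peaks assigned to Soga1 (5.73-fold), Lgi2 (5.19-fold), Scfd2 (4.92-fold), Shisal1 (4.89-fold) and Adamts7 (4.30-fold) followed, then Slc39a11, Septin11, Elk3, Vmp1 and Scnn1b between 4.19-fold and 3.82-fold. An intergenic peak on chromosome 1 at 24612395 to 24613180 went from 9377 to 55448 normalized reads, 5.91-fold, close to the 5.41-fold of the mitochondrial genome. The nearest protein-coding gene to it, Col19a1, is 24473 bp away. In the other direction, a peak in the gene body of Fbxo38 on chromosome 18 at 62531537 to 62532060 was 4.40-fold lower, from 130 to 23 reads. Peaks of Ankrd44 (4.11-fold), Zfp800 (3.61-fold), Wdfy4 (3.58-fold), Ryr2 (3.54-fold), Slc9a9 (3.45-fold), Stk35 (3.25-fold), Grsf1 (3.19-fold), the stem cell transcription factor Mecom (3.15-fold), Slc35f1 (2.96-fold), Mast4 and Syne3 (each 2.92-fold) were also lower.

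Changed peaks lay less often than the others at gene ends, here within 1 kb of either end of a protein-coding gene. Of the higher peaks 7.12% (6.28 to 8.04) and of the lower peaks 3.84% (2.91 to 4.97) were at gene ends, against 20.3% of the others. Intergenic peaks made up 49.0% of the higher, 47.9% of the lower and 37.7% of the other peaks. Gene-end peaks were also stronger, with a median signal of 225 against 52.7 for intergenic peaks. The share of peaks at least 2-fold higher fell from 14.2% in the lowest signal decile to 0.013% in the highest. Places were not compared at like signal, so how far the low gene-end share follows signal stays open. Median log2 ratios of the 19 autosomes lay between -0.04 and 0.02, with the X chromosome at -0.10 over 1486 peaks and the Y at 0.17 over 15 peaks.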

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

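The tests in this part were chosen after the results were seen, except the loess correction alone, which was planned; reading it as a test of the trend came after. The mitochondrial genome, which the comparisons leave out, took 31.2% of reads in peaks in the ablation library (31.2 to 31.3) against 7.31% in control (7.30 to 7.32), a signal above the control level in data outside the main measurement.

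The EMT and inflammatory lists lay above and the spinous list below random lists. With loess-corrected ratios and random lists matched on mean signal per peak, all 3 lists still lay outside the central 95%. The correction and matching thus did not remove their calls. These 3 lists were grouped after the results were seen, so that all of them passed is no evidence against the higher ratios of weak peaks as a cause. With loess alone the lists of hair follicle stem cell (99.6th percentile), wound-front migration (99.1), extracellular matrix (98.3) and glycolysis genes (98.9) also stayed above, but with the matching added the hair follicle list was at 97.6, within Monte Carlo error of the limit, and 0 of the other 3 stayed above, so for these 4 lists the trend stays open; for endothelial markers, at 90.6 with loess alone (median 0.18 against 0.29 before), it may account for the call. Fibroblasts in the ablation sort might raise mesenchymal genes; the α6 integrin and lineage reporter gates should remove them, their markers had a median log2 ratio of 0.16 (Col1a1 -0.02, Dcn 0.23), and 4 of 8 markers measured are too few to decide. Ablation itself, any difference between the animals and any difference between the library preparations stay open and untested. With no replicate library in either group, these causes cannot be separated by design.

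The peak nearest to Col19a1 was 5.91-fold higher. Its ratio divided by that of the mitochondrial genome was 1.09, and a candidate explanation is mitochondrial reads placed on a nuclear copy of mitochondrial sequence. A gain of the whole region is argued against by the 29 other tested peaks within 1 Mb, whose median log2 ratio was -0.13. No biological explanation was tested.

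Peaks of the Y-linked genes Eif2s3y, Uty and Ddx3y were 2.65-fold higher in ablation (1.95 to 3.63; 64 and 132 reads in 4 peaks), and Xist was at 0.573-fold (0.468 to 0.697). By gene, Uty was at 3.24-fold (2.08 to 5.16), Ddx3y at 2.97-fold (1.5 to 6.2) and Eif2s3y at 1.69-fold with an interval that includes 1 (0.940 to 3.09). A larger share of male cells in the ablation library would give both, and is a candidate explanation. Among peaks of like signal the median log2 ratio was 0.15, with 0.84 at 1 SD above it. The pooled lower bound, 0.97, lay above both, which argues against the median trend alone as the cause for the pooled peaks. That limit is weak, since 10.3% of peaks of like signal were at least 2-fold higher, so the scatter of weak peaks is not set aside. The 15 tested Y peaks together had a median of 0.17. Eif2s3y alone (log2 0.76) did not pass the limit. Nor did Ddx3y alone, whose lower bound of 1.5-fold falls below it. The labels give no sex, so a difference in sex and the ablation cannot be separated by design.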

How the results depend on the processing

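Tests with a binomial model, nuclear totals, removal of peaks above 5000, peaks within 5 kb and matching on signal per peak were chosen after seeing the data; the others were fixed before. Peaks at least 2-fold higher and lower numbered 3412 and 1432. They became 1224 and 441 with a larger pseudocount (10), 5190 and 2519 without the filter, 1785 and 746 with a filter at the 25th percentile, 1341 and 4232 with table totals, 5367 and 805 with centring on strong gene-end peaks, 9930 and 5691 at 1.5-fold and 667 and 196 at 3-fold. A binomial test of the recovered reads, which compares libraries and not conditions, called 7261 and 9490. Thresholds and filters change the counts by construction, and table totals carry the mitochondrial reads; otherwise the cause was not tested. Counts stayed within 1.5 times with a smaller pseudocount, median centring, the loess correction, nuclear totals, autosomes alone and without peaks above 5000.

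The median log2 ratio, -0.01, was -0.0056 without the filter, -0.032 at the 25th percentile, -0.35 with table totals, -0.00012 and 0 after median centring and loess, which fix it, 0.16 with gene-end centring and 0.075 with nuclear totals. The gene-end share of higher peaks, 7.12%, was 6.21% with the larger pseudocount, 8.40% at the 25th percentile, 5.52% with table totals, 6.26% after loess, 9.0% at 1.5-fold and 5.55% at 3-fold. That of lower peaks, 3.84%, was 5.29% with table totals, 5.62% at 1.5-fold and 2.04% at 3-fold. All stayed below the 20.3% of other peaks in the reported setting.

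Lists above the random lists numbered 7, also with loess alone, where actomyosin genes took the place of endothelial markers, and 8 with the filter at the 25th percentile, wound keratins added. They numbered 2 with peaks outside gene ends, 4 with the highest peak per gene, 3 with matching on signal per peak and 4, interferon response among them (98.3rd percentile), with that matching and loess together. Lists below numbered 1, and 2 with the highest peak per gene, EGF receptor family genes added, and 0 with peaks within 5 kb; with gene-end peaks alone the 1 list below was melanocyte markers, not spinous genes. Over 19 settings, the reported one included, EMT and hair follicle stem cell lists stayed above in 18, inflammatory genes in 17, migration in 15, extracellular matrix and glycolysis in 14 and endothelial markers in 12. Spinous genes stayed below in 17. Table totals, nuclear totals, median centring and gene-end centring shift all genes nearly alike, so a list could hardly change place under them. Those settings therefore add little to these counts. With table totals the medians of migration (-0.28), extracellular matrix (-0.29), inflammatory (-0.20), hair follicle stem cell (-0.21) and endothelial genes (-0.042) changed sign with the shift of all genes, and stayed above the random lists. The glycolysis median changed sign with gene-end centring (0.16), loess (0.090), nuclear totals (0.070), gene-end peaks alone (0.0084), the highest peak (0.054) and the median of peaks (0.044). With the highest peak, migration was at -0.062 and extracellular matrix at -0.013; the cause was not tested.

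Of 135 named genes, 31 changed sign with table totals, 23 with gene-end centring and 9 with loess; these shifts are too small to turn a large ratio, so the sign of such ratios was not put to the test. Motif alternatives and leaving out replicates could not be run. At a 2-fold threshold, true 2-fold changes fall on either side of it (46% of the simulated gains were recovered), and single weak peaks rest on few reads.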

Other observations

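The genes of this part were chosen after their values were seen. Several genes were more accessible at many of their peaks in ablation, and others less. At Shisal1 5 of 5 peaks were at least 2-fold higher in ablation (4.04-fold over the gene, 3.38 to 4.86), at St6galnac3 5 of 6 (2.84-fold, 2.3 to 3.5), and at Rin3, a regulator of endocytic trafficking, 6 of 10 (2.25-fold, 1.99 to 2.54). The Wnt ligand gene Wnt7a had 6 of 12 peaks higher (1.77-fold, 1.61 to 1.95), the ETS factor Elk3 6 of 14 (1.81-fold, 1.66 to 1.98), the epithelial sodium channel gene Scnn1b 5 of 9 and the transcription factor Prdm16 5 of 11 (1.72-fold, 1.56 to 1.90). At none of these 7 genes was a peak at least 2-fold lower. In the other direction Slc35f1 had 8 of 16 peaks at least 2-fold lower (0.536-fold, 0.483 to 0.595), the phospholipase gene Pla2g4a 4 of 8 (0.636-fold, 0.563 to 0.717), the potassium channel gene Kcnh5 3 of 3 (0.337-fold, 0.236 to 0.472) and Skint4 3 of 3 (0.386-fold, 0.282 to 0.521). A count of higher peaks did not always go with a higher sum: Trabd2b had 6 of 34 peaks higher at 0.999-fold, and Lipc 6 of 16 at 1.16-fold.

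A cluster of 3 peaks at the predicted gene Gm13286 on chromosome 4, 88757515 to 88763722, was far lower in ablation, with 317 reads in control and 21 in ablation (0.0851-fold, 0.0520 to 0.132). The 6 peaks flanking it were at 0.977-fold (0.908 to 1.05).

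The table runs through its sorted peak names 3 times, and the file does not say why. Peaks first listed in the first run (9840) were higher in ablation in 90.2% of cases, those of the second (8075) in 17.6% and those of the third (66676) in 47.2%. Of the tested peaks at least 2-fold higher and lower, the first run held 1790 and 2, the second 12 and 729 and the third 1610 and 701. If the runs follow peak calling in ablation alone, in control alone and in both, which the file does not state, the counts of peaks past 2-fold partly follow that calling.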
